A study of Homo sapiens with 2 samples.

How the data were processed

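The data are RNA-seq of HCT15 colon cancer cells. Per the labels' protocols, cells were transfected with 100 to 200 pmol of an siRNA against FSCN1 or of a non-silencing siRNA, total RNA was isolated, and 150 bp paired reads were sequenced. There was 1 library per group. The siRNA sequences, the time after transfection, strand use and the number of separate cultures are not given in the sources used here.

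Per the submitters' processing notes, HISAT2, SAMtools, HTSeq and Cufflinks were used with the hg19 genome build, with no versions or roles stated. The gene models are not given in the sources used here. Per the file headers, the deposited table is in the gene-level layout of Cuffdiff, with an FPKM value for each library, computed by the authors. Per the file headers it also holds the authors' log2 fold, a test statistic (a score), a p-value and a q-value, and the authors' call for each gene. How the FPKM of the libraries were scaled to each other is not given in the sources used here. FPKM divides fragments by transcript length and total, so a few very abundant genes can shift all others, and a gene's value depends on the transcript models assigned to it.

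The deposited table had passed through a spreadsheet. In 2193 genes listed at 0 in the FSCN1 siRNA library the log2 fold was a text error in place of minus infinity, and 27 gene symbols had become dates. All 27 were recovered through their Ensembl identifiers. GENCODE release 29, which is on another genome build, was used only for gene symbols, gene types, transcript lengths and 3' UTR sequences, never for coordinates: 56682 identifiers matched it and 5558 did not. Coordinates are those of the deposited table on hg19, written 1-based, and a locus there can span several neighbouring genes. Listed values of exactly 0 may be failed estimates, since 39175 genes were at 0 in both libraries, the stress-inducible chaperone genes HSPA1A and HSPA1B among them, so no fold is given against 0.

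The planned tests assumed counts. The table held FPKM, so the rule written for that case was used. The log2 ratio was log2 of FPKM plus 0.1 in the FSCN1 siRNA library minus the same in the control library. Genes with mean FPKM of at least 1 entered, and at least 2-fold was the size rule. With 1 library per group no p-value across genes was computed. For gene lists, the median over measured members was ranked among 10000 random lists of the same size, matched on mean FPKM in 20 bins, and given with an order-statistic 95% interval over members. These percentiles describe the libraries and are not tests between the conditions. The 36 lists, the named genes rule and the main alternatives were fixed before the data were examined, and 7 further lists were written after. FSCN1 is in none of the 36.

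Depth was estimated from the step between low FPKM values of genes with a single transcript over 3000 nt. With the estimated step, 87.5% of low values in the control library and 85.1% in the FSCN1 siRNA library lay within 0.1 of a whole number of fragments. The depths were about 13780000 and 14650000 fragments, a ratio of 1.063, and carry any scaling the authors applied between the libraries. Intervals for FSCN1 and LYAR used these depths and the median annotated transcript length, 713 and 1124 nt, so they are approximate and cover counting error only. The FPKM values summed to 851029 and 729823.

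Named genes were FSCN1 and LYAR, the 12 genes with the highest and the 12 with the lowest ratio at mean FPKM of at least 5 (leaving out uncharacterised, pseudogene and read-through models), and up to 4 measured members of each described list with the largest absolute log2 ratio. For a list that did not stand apart, up to 2 of its most highly expressed members could be added. Genes outside this rule are said to be chosen after their values were seen or named as the single exception of a count. Some genes that the rule selects are not reported here. Genes with near-identical copies, overlapping genes and antisense genes are uncertain, since strand use is not stated.

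The rule was tested on simulated data with counting error only, at 1 depth near the estimates and 1 transcript length for all genes. Of 100 genes changed 3-fold, 97.0% passed it, and of 100 genes changed 1.5-fold, 0.0% passed. Of 12729 unchanged genes, 1 passed. The counting error of shorter transcripts is larger than in this simulation. Alternatives were median-ratio scaling, scaling to the same FPKM total, no filter, mean FPKM of at least 5, a pseudocount of 1, protein-coding genes only, fold sizes of 1.5 and 3, unmatched random lists and the mean over members. After the data were seen, genes tested by the authors only and genes not listed at 0 in a library were added. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.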

Results

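RNA was sequenced from HCT15 cells, an established human colon cancer line, after transfection with an siRNA against FSCN1 or with a control siRNA. FSCN1 encodes fascin, a protein that bundles actin filaments. There was 1 library per group, so no value here has a replicate check, and each comparison is between 2 libraries. The gene table listed 62240 genes with an FPKM value in each library, and 12929 of them had a mean FPKM of at least 1. The spacing of the low FPKM values put the depth at about 13780000 fragments in the control library and 14650000 in the FSCN1 siRNA library. At that depth 1 FPKM equals about 13.8 and 14.6 fragments per kilobase of transcript. Across the 12929 genes the log2 FPKM values of the libraries had a correlation of 0.877, genes not being independent replicates. Ratios are given as log2 of FPKM plus 0.1 in the FSCN1 siRNA library over the control library, which understates the difference of low genes.

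The first question was whether the siRNA target itself was lower. FSCN1 (ENSG00000075618, hg19 chromosome 7, 5632447 to 5646286) stood at 144 FPKM in the control library and 43.8 FPKM in the FSCN1 siRNA library, a log2 ratio of -1.71. The level that remained was 30.5% of control, with an approximate 95% interval of 27.3% to 33.8% that covers counting error only. Of the 12929 genes, 397 (3.1%) had a lower ratio than FSCN1. The authors' deposited table gave FSCN1 a q-value of 0.225 and did not call it. LYAR, a nucleolar protein gene that the series title places upstream of FSCN1, read 63.3 FPKM in the control library and 48.0 FPKM in the FSCN1 siRNA library. Its log2 ratio was -0.40, or 75.8% of control (68.9% to 83.3% from counting error), and 33.2% of genes had a lower ratio. The interval does not cover the choice of scaling: with libraries scaled to the same FPKM total the log2 ratio of LYAR was -0.18. In the authors' deposited table the q-value of LYAR (ENSG00000145220, chromosome 4, 4269428 to 4291881) was 0.9996.

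At the upper end of the comparison, NUPR1, a stress-induced nuclear protein gene, was 95.4-fold higher (0.382 to 45.9 FPKM), and INHBE, which encodes an inhibin subunit, was 71.8-fold higher (0.280 to 27.2 FPKM). S100P, a calcium-binding protein gene, read 15.7 FPKM in the control library and 1010 FPKM in the FSCN1 siRNA library, 64.3-fold higher. SPRR2D was 86.4-fold higher, the hexokinase family gene HKDC1 45.4-fold and the matrix metalloproteinase gene MMP10 83.1-fold. These folds depend on the added 0.1: with a pseudocount of 1 the log2 ratios were 5.08 in place of 6.58 for NUPR1, 4.46 in place of 6.17 for INHBE, 5.09 in place of 6.43 for SPRR2D, 4.92 for HKDC1 and 3.63 in place of 6.38 for MMP10. MMP3, whose locus in the table spans the same interval as that of MMP10, was listed at 0 in the control library and at 12.5 FPKM in the FSCN1 siRNA library. DDIT4-AS1 was 51.3-fold higher, and it overlaps DDIT4, from which its fragments cannot be separated unless strand was used. RNU4-2, MIR3648 and RB1-DT were listed at 0 in the control library against 113, 64.2 and 12.1 FPKM, and RN7SK read 0.00638 and 29.3 FPKM (log2 ratio 8.11, or 4.91 with a pseudocount of 1). RNU4-2, MIR3648 and RN7SK are short transcripts with near-identical copies in the genome, so their levels are uncertain.

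At the lower end, HSPA8, the constitutive cytosolic HSP70 chaperone gene, read 1210 FPKM in the control library and 90.8 FPKM in the FSCN1 siRNA library, 13.3-fold lower. SLC40A1, the iron exporter ferroportin, was 16.6-fold lower, the glutathione peroxidase gene GPX2 10.7-fold and the tetraspanin gene CD82 10.7-fold. RASL11A was 14.7-fold lower, HLA-E 13.6-fold, LINC01605 11.3-fold, RGN 9.32-fold, SULT2A1 9.28-fold and GPR157 8.78-fold. VIM-AS1, antisense to the vimentin gene VIM, was 8.88-fold lower. VAMP7, which has a copy on each sex chromosome in the annotation, was 25.1-fold lower, and its log2 ratio was -4.65 both for the X copy and for the sum of the copies. With a pseudocount of 1 the log2 ratio was -3.40 for VAMP7, -2.97 in place of -4.06 for SLC40A1, -2.55 in place of -3.42 for CD82, -2.60 in place of -3.49 for LINC01605 and -2.58 in place of -3.21 for SULT2A1. HLA-E has close paralogs and HSPA8 has processed pseudogenes, so reads could be split among copies.

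Of the 12929 genes, 1764 were at least 2-fold higher and 1458 at least 2-fold lower in the FSCN1 siRNA library, together 24.9% of them. Among the 11058 protein-coding genes the counts were 1211 higher and 1242 lower. The median log2 ratio of all genes was -0.06 with an SD of 1.14. Scaling each library to the same FPKM total moved that median to 0.18, and 2641 genes were then higher and 1042 lower, a share of 71.7% higher against 54.7%. In simulated libraries that differed by counting error alone, with a 2 kb transcript for every gene, 1 of 12729 unchanged genes passed the 2-fold rule. Shorter transcripts have more counting error than this, and variation between cultures was not measured. The authors' deposited table called 87 of 14881 tested genes, 63 higher and 24 lower. Of these, 67 met the 2-fold rule used here, and the other 20 were under its filter on mean FPKM. Among the 87, 11 were listed at 0 in the control library and 14 in the FSCN1 siRNA library. The called genes listed in the authors' deposited table included DDIT4, ASNS and S100P among the higher and HSPA8 and RASL11A among the lower.

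**Figure D1:**
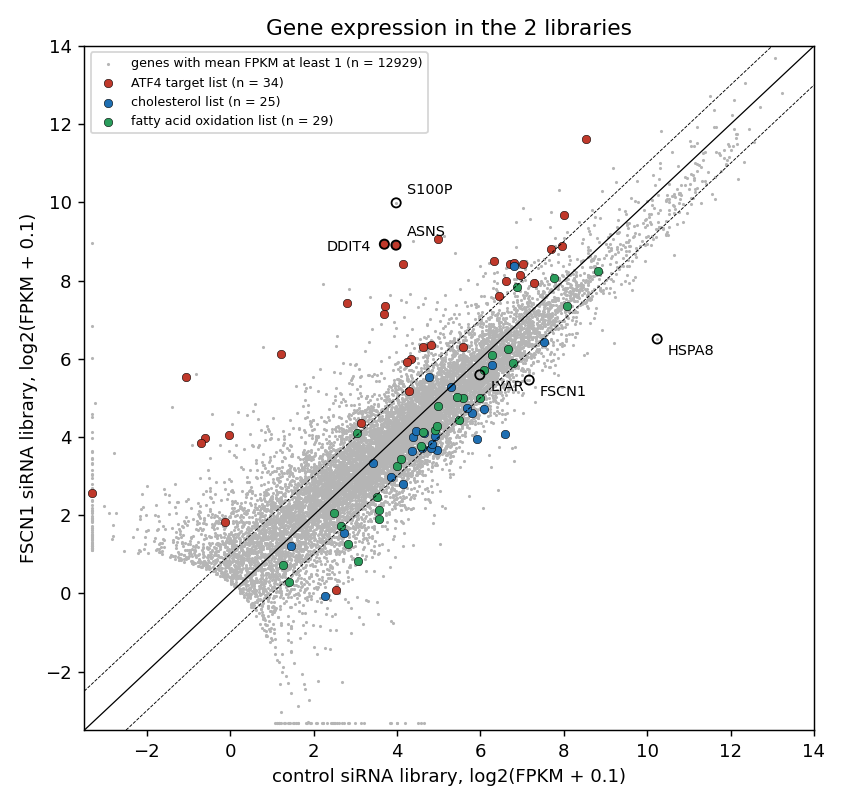
Each point is 1 gene with mean FPKM of at least 1 (12929 genes), placed by log2(FPKM + 0.1) in the control siRNA library (x) and in the FSCN1 siRNA library (y); the solid line marks equal levels and the dashed lines a 2-fold difference. ATF4 targets (red) lie mostly above the upper dashed line, 29 of 34 of them at least 2-fold higher, while FSCN1 lies below the lower line at a log2 ratio of -1.71.

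The series title names fatty acid metabolism, so genes of fatty acid handling were compared next. Fatty acid oxidation genes were lower as a group: the median log2 ratio of 29 measured genes was -0.68 (95% interval over members -0.92 to -0.44), at the 0.06th percentile of 10000 random lists matched on mean FPKM. Of these, 7 were at least 2-fold lower and 1 was at least 2-fold higher. The peroxisomal oxidase gene ACOX3 (log2 ratio -2.24), CPT1C (-1.67), the peroxisomal bifunctional enzyme gene EHHADH (-1.57) and the acyl-CoA dehydrogenase gene ACADSB (-1.45) had the lowest ratios. Fatty acid synthesis and desaturation genes had a median of -0.36 over 20 genes (9.27th percentile), with 5 at least 2-fold lower and 1 higher, and so did not stand apart from matched lists. In that group TECR, the reductase of very long chain fatty acid elongation, read 207 and 61.2 FPKM, ACACB 2.11 and 0.558 FPKM, SCD5 4.41 and 1.93 FPKM, and FADS3 21.8 and 55.5 FPKM. FASN, chosen after its values were seen, had a log2 fold of -0.60 and SCD one of -0.58 in the authors' deposited table, neither called. The 27 measured genes of fatty acid uptake, activation and lipid droplets had a median of -0.20 (20.39th percentile), which was 0.01 with libraries scaled to the same FPKM total, and its members went both ways. ACSL5, an acyl-CoA synthetase gene, read 1.42 and 28.4 FPKM (log2 ratio 4.23) and PNPLA2, the adipose triglyceride lipase gene, 79.0 and 187 FPKM, whereas ACSL6 (-3.25), CIDEC (-2.20) and FABP1 (-2.11) were lower. With a pseudocount of 1 the log2 ratio was 3.60 for ACSL5, -2.31 for ACSL6, -1.10 for CIDEC, -1.50 for FABP1 and -1.0 for ACACB.

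**Figure D2:**
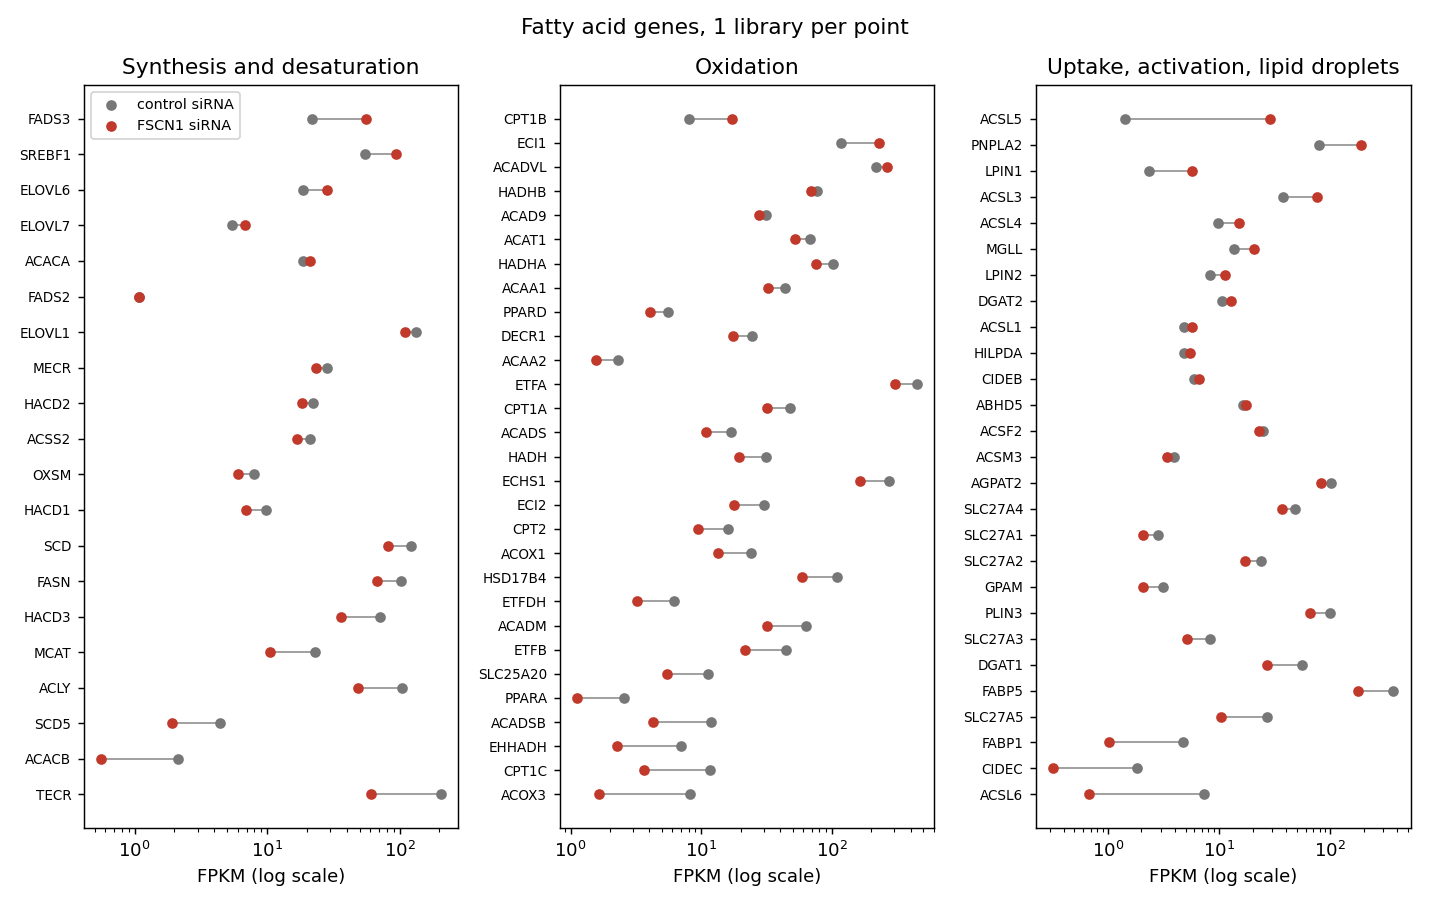
FPKM on a log axis of each measured gene of fatty acid synthesis (20), oxidation (29) and uptake or storage (27), in the control siRNA library (grey) and the FSCN1 siRNA library (red), 1 library per point, ordered by ratio. In the oxidation panel 7 genes are at least 2-fold lower and 1 is at least 2-fold higher, and in the uptake panel ACSL5 goes from 1.42 to 28.4 FPKM.

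Cholesterol synthesis genes were lower too. The 25 genes had a median log2 ratio of -0.90 (-1.19 to -0.43, 0th percentile), with 11 at least 2-fold lower. DHCR7, which encodes an enzyme of the last steps of cholesterol synthesis, read 60.7 and 15.4 FPKM, a log2 ratio of -1.97. Genes of the TCA cycle and nuclear-encoded oxidative phosphorylation had a median of -0.65 over 41 genes (0.14th percentile), 9 of them at least 2-fold lower and 0 higher, with UQCRC2 at -1.65 and ATP5F1A at -1.63. The 13 mitochondrially encoded genes had a median of 0.32 (99.69th percentile), MT-CO1 reading 2910 and 6700 FPKM, although this list was at the 89.89th percentile without matching on expression. Glycolysis and hypoxia genes, pooled in a single list, did not stand apart (median -0.41, 32 genes, 12.23rd percentile). LDHA (-1.87) and GPI (-1.66) were lower and VEGFA, the angiogenic growth factor gene, was higher (3.34). The glycolytic enzyme genes were mostly lower, but were not ranked apart from the hypoxia genes. Chosen after their values were seen, PGAM1 (-1.59), ALDOA (-1.23), PKM (-1.08), PGK1 (-1.04) and GAPDH (-0.93) were lower. The hexokinase genes HK2 (1.37) and HK1 (1.14) were higher.

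The highest median of the 35 ranked lists was that of the integrated stress response, genes induced by the transcription factor ATF4 when amino acids are scarce or translation initiation is restrained. Its 34 measured genes had a median log2 ratio of 1.69 (1.41 to 4.08, 100th percentile), and 29 were at least 2-fold higher. Besides NUPR1, DDIT4, an inhibitor of mTORC1 signalling, read 12.9 and 488 FPKM, and ASNS, asparagine synthetase, 15.6 and 480 FPKM. FGF21 was listed at 0 in the control library and at 5.78 FPKM in the FSCN1 siRNA library. PHGDH, a serine synthesis gene named here because it was the 1 member at least 2-fold lower, read 5.71 and 0.969 FPKM. The authors' deposited table called 10 of the list's genes, against 0.2 expected from the share of all tested genes called. Those calls come from the same 2 libraries, so they are not separate support for the list.

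Growth factor and inflammatory response genes were also higher. Immediate early and MAPK feedback genes had a median of 1.13 over 28 genes (0.77 to 1.99, 100th percentile), 17 at least 2-fold higher and 0 lower, with KLF10 at 3.35, PHLDA1 at 3.27, the ERK phosphatase gene DUSP6 at 2.85 and EGR1 at 2.61. Interferon response genes had a median of 0.87 over 32 genes (100th percentile), with 14 at least 2-fold higher and 3 lower; ISG20 had a ratio of 3.01, RSAD2 2.96, OAS2 2.86 and the interferon lambda gene IFNL1 2.57. NF-kB and inflammatory genes had a median of 0.71 over 17 genes (99.59th percentile), with the chemokine genes CXCL2 (4.25), CXCL1 (4.10), CXCL8 (3.79) and CXCL3 (2.40) highest. With a pseudocount of 1 the log2 ratio was 2.55 for CXCL2, 2.44 for CXCL1, 1.73 for CXCL8, 2.28 for RSAD2 and 1.56 for OAS2. Those chemokines were low in both libraries, and with genes of mean FPKM of at least 5 the median was -0.05. CDK inhibitors and p53 targets, pooled in a single list, had a median of 0.26 over 29 genes (99th percentile, 94.44th without matching). CDKN2B (2.44), GADD45A (2.29) and GADD45B (2.15) were higher and CDKN1C (-2.53) lower. Members chosen after their values were seen also went both ways. FDXR (-1.64) and CCNG1 (-1.48) were lower, BBC3 (1.42) and TNFRSF10B (1.06) higher, and CDKN1A was at 0.47. The median therefore does not show a rise of p53 targets as a group. Apoptosis regulators lay just inside the range of matched lists (0.23, 25 genes, 97.04th percentile), PMAIP1, the NOXA gene, reading 3.33 and 40.5 FPKM.

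Heat shock protein and ER chaperone genes were lower. Heat shock protein genes had a median of -1.06 over 17 genes (-1.31 to -0.56, 0th percentile), with 9 at least 2-fold lower and 0 higher. After HSPA8, the lowest were DNAJA1 (-1.73), HSPE1 (-1.61) and HSP90AA1 (-1.47), while HSPA1A and HSPA1B were listed at 0 in both libraries. ER chaperones had a median of -0.86 over 23 genes (-1.09 to -0.02, 0.01st percentile), 9 at least 2-fold lower and 2 higher, with PDIA4 at -2.40, SDF2L1 at -2.28, the calcium-binding chaperone gene CALR at -1.99 and CRELD2 at -1.78. NRF2 targets and antioxidant genes had a median of -0.78 over 23 genes (0.1st percentile), 8 at least 2-fold lower and 2 higher. GPX2 (-3.42), SLC40A1 (-4.06) and UGT1A6 (-2.52), which shares exons with other UGT1A genes, were lower, and the cystine transporter gene SLC7A11, which is also an ATF4 target, was higher (4.55, or 3.33 with a pseudocount of 1).

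Because fascin acts on actin, cytoskeletal and adhesion genes were compared. Actin bundling and filopodia genes did not stand apart (median 0.05, 28 genes, 92.06th percentile): villin, VIL1, read 249 and 38.8 FPKM, whereas FMNL1 (1.97, or 1.34 with a pseudocount of 1) and CDC42EP1 (1.78) were higher. Actin regulators and contractile genes had a median of -0.29 over 34 genes (59.95th percentile), with CNN2 (-2.19) and the myosin light chain gene MYL9 (-2.04) lower and RHOB higher (1.83). The actin genes ACTB and ACTG1, its most abundant members, had ratios of -1.60 and -1.54. Integrin and focal adhesion genes (-0.05, 26 genes, 81.88th percentile) included ITGA2 at 1.90 and LAMB3 at 1.51, and their median was 0.18 with libraries scaled to the same FPKM total. Epithelial junction genes had a median of 0.12 over 33 genes (98.01st percentile) but a mean of -0.04, and CLDN2 (-2.69) and ST14 (-1.63) were lower. Mesenchymal genes had 9 measured members and a median of -0.11 (30.01st percentile, 0.16 at the same FPKM total), with SPARC (-3.77, or -1.88 with a pseudocount of 1) and VIM (-2.89) lower. Matrix proteases had a median of 0.23 over 13 genes (95.51st percentile) that was -0.55 with no filter on mean FPKM. Besides MMP3 and MMP10, the collagenase gene MMP1 read 5.85 and 95.7 FPKM and the urokinase receptor gene PLAUR 12.2 and 61.5 FPKM. MMP15 (37.8 and 15.5 FPKM) and MMP14 (162 and 91.0 FPKM), chosen after their values were seen, were lower.

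Among proliferation and growth lists, G1/S and DNA replication genes were lower, with a median of -0.56 over 40 genes (-0.69 to -0.32, 0.08th percentile) and 8 at least 2-fold lower. ORC1 (-1.55), the polymerase gene POLD1 (-1.44), GINS1 (-1.42) and UNG (-1.21) had the lowest ratios, while PCNA read 412 and 373 FPKM. G2/M and mitosis genes lay within matched lists (-0.30, 37 genes, 34.14th percentile), with CCNB1 at -1.55 and AURKA at -1.39. Cytosolic ribosomal protein genes had a median of -0.54 over 45 genes, which at their high expression was the 16.99th percentile, and ribosome biogenesis genes, the list that holds LYAR, one of -0.19 over 44 (58.54th percentile, 0.03 at the same FPKM total). NHP2, a subunit of box H/ACA particles, had the lowest ratio of the latter (-1.93).

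Differentiation and signalling lists mostly held genes that went both ways. Enterocyte genes had a median of -0.54 over 16 genes (1.9th percentile) with 7 at least 2-fold lower and 6 higher, and 0.01 with genes of mean FPKM of at least 5. KRT20 (-2.95) and SLC26A2 (-2.85) were lower and CEACAM5 higher (2.76). Goblet and secretory genes (0.12, 6 genes, 64.43rd percentile) included TFF1 at 2.99 and SPINK4 at -2.90. WNT targets (-0.08, 19 genes, 65.66th percentile, 0.14 at the same FPKM total) included SOX9 at 2.33 and the stem cell receptor gene LGR5 at -1.71. YAP/TAZ targets had a median of 0.33 over 17 genes (92.72nd percentile), with ANKRD1 at 2.88. TGF-beta targets had one of -0.29 over 17 (23.38th percentile, 0.07 at the same FPKM total), with BHLHE40 at 2.63 and SMAD6 at -2.25. Autophagy and lysosome genes had a median of -0.12 over 27 (70.43rd percentile, 0.11 at the same FPKM total), with WIPI1 (2.71) and MAP1LC3B (2.22) higher. Metallothionein and zinc transport genes (0.05, 6 genes, 71.27th percentile) included MT1X at -3.06. Replication-dependent histone genes (0.62, 8 genes, 92.73rd percentile) included HIST1H4H at -2.16 and HIST1H2AC at 2.09. Of the markers of other cell types, 1 immune gene was measured, LYZ (-0.05), and 3 fibroblast or endothelial genes had a median of -0.11 (38.97th percentile, 0.11 at the same FPKM total), with COL3A1 at 3.36 and 0.0843 FPKM. With a pseudocount of 1 the log2 ratio was -1.54 for KRT20, 1.86 for CEACAM5, -2.09 for SPINK4 and -1.24 for HIST1H4H.

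**Figure D3:**
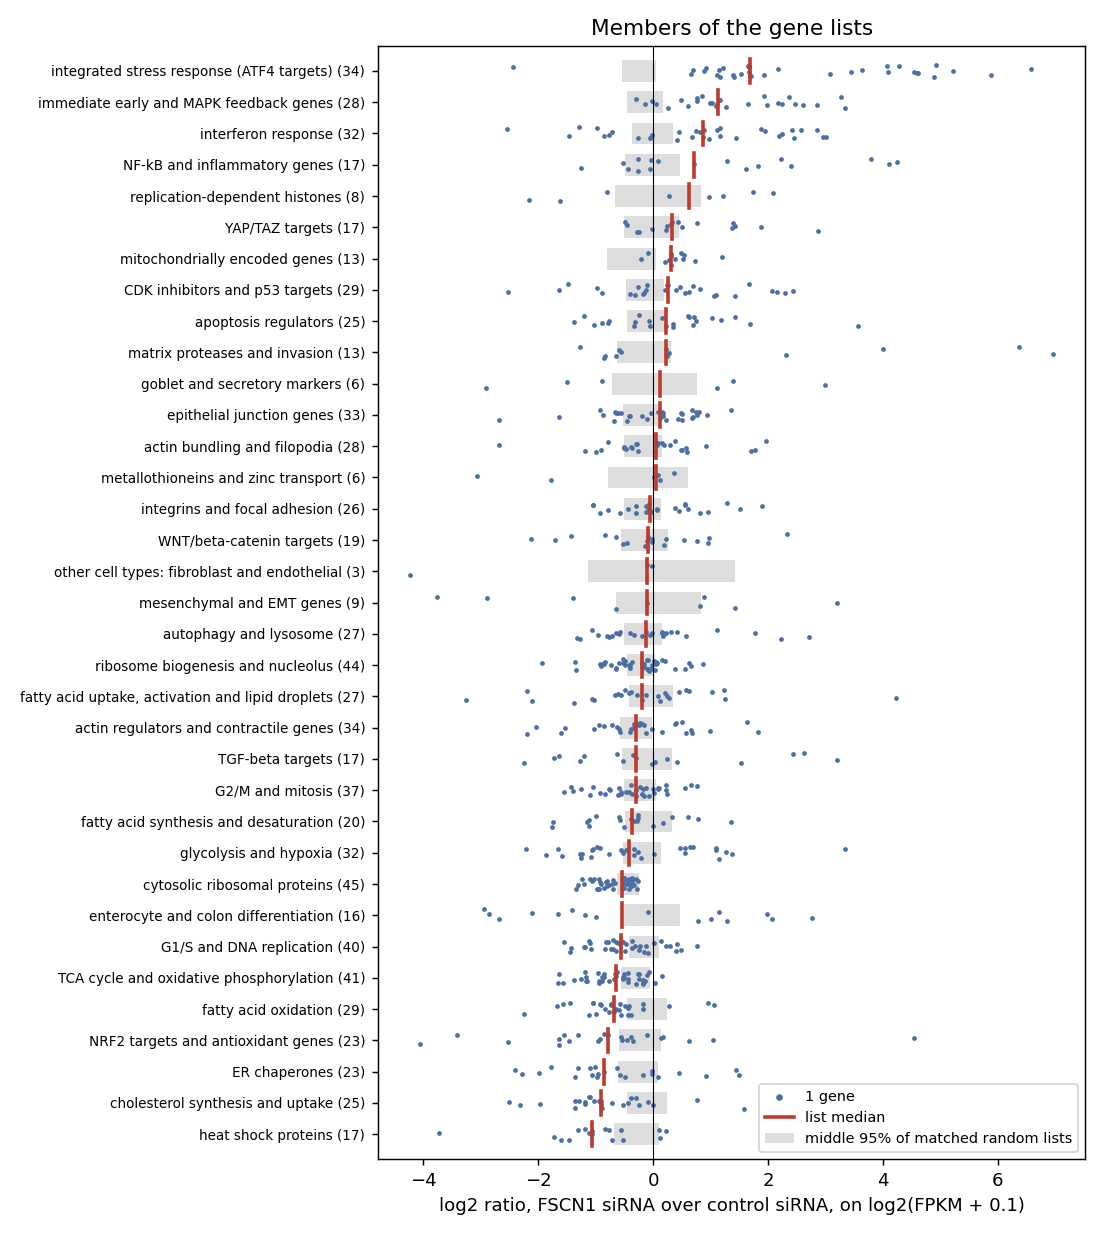
Each row is a gene list fixed before the data were examined, with its number of measured genes; points are genes, red bars list medians and grey boxes the middle 95% of 10000 random lists matched on mean FPKM, on the log2 ratio axis. Of 35 lists, 7 medians lie above the grey box and 8 below it, where random lists of genes would give 0.9 on each side. Genes of a list can vary together between cultures, so these counts are not evidence of an siRNA effect. Genes listed at 0 in a library are placed by the added 0.1.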

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

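Restricting to genes tested by the authors and leaving out genes listed at 0 were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group had 1 library, and no library could be left out for the same reason. The counting-interval condition and the count-based scalings were not run, since the table held no counts. Scaling to the same FPKM total gave FSCN1 a log2 ratio of -1.49. The same scaling gave list medians of -0.08 for G2/M, -0.43 for the TCA cycle and oxidative phosphorylation, -0.32 for cytosolic ribosomal proteins, 0.03 for ribosome biogenesis and 0.11 for fibroblast and endothelial markers, the last 2 on the other side of 0. The counts of higher and lower genes were 4779 and 3072 with no filter, 3094 and 3171 at 1.5-fold, and 814 and 499 at 3-fold, and with mean FPKM of at least 5 there were 947 higher and 1018 lower, a share of 48.2% higher against 54.7%. Histone genes had a median of -0.05 with no filter, and with mean FPKM of at least 5 NF-kB genes had -0.05 and enterocyte genes 0.01; these lists then held other members. With the mean over members, epithelial junction genes were at -0.04 and the 68.74th percentile, enterocyte genes at the 11.25th and mitochondrially encoded genes at the 96.77th, all back within matched lists. The mean put 4 lists outside that were inside by the median: matrix proteases (99.97th percentile), YAP/TAZ targets (97.66th), cytosolic ribosomal proteins (0.04th) and fibroblast and endothelial markers (1.95th). Without matching on expression, epithelial junction genes (84.32nd), CDK inhibitors and p53 targets (94.44th) and mitochondrially encoded genes (89.89th) were inside, and glycolysis (2.14th) and cytosolic ribosomal proteins (0.01st) outside. For these lists the cause was not tested. Of 314 list medians recomputed under alternatives, 19, from 14 lists, changed sign. The histone, NF-kB, enterocyte and epithelial junction medians were 4 of these, the lists that stood apart or had medians of large size. Others not yet given were, for integrins, 0.01 with median-ratio scaling and 0.13 by the mean, for fatty acid uptake 0.10 with mean FPKM of at least 5, for matrix proteases -0.16 without genes listed at 0, and by the mean 0.04 for TGF-beta targets and -0.71 for metallothioneins. Between pseudocounts of 0.1 and 1, 33 of 171 ratios of genes named by ratio or leading a list moved by over 1.5 times and 0 changed sign. Depth limits genes near 1 FPKM, where a transcript of 1 kb has about 14 fragments.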

Other observations

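The lists of tRNA synthetases, transporters, proteasome subunits, snoRNA hosts, fibroblast transcripts and cancer-testis antigens, the 7-mer scores, the comparison by gene type and the tests of explanations in this part were chosen after the results were seen, as were the genes named outside the lists; the ATF4 and ER chaperone lists were fixed before. Cytosolic aminoacyl-tRNA synthetase genes, whose products charge tRNAs for translation, had a median log2 ratio of 0.55 over 19 genes (99.98th percentile of matched lists), with SARS (1.65), CARS (1.42) and GARS (1.41) higher and QARS (-1.62) lower. Without the 4 genes shared with the ATF4 list the other 15 had a median of 0.25 (98.46th percentile). The mitochondrial synthetases had a median of -0.55 over 16 genes (1.29th percentile), 4 at least 2-fold lower and 0 higher, with SARS2 at -1.65 and FARS2 at -1.53. Amino acid transporters had a median of 0.93 over 18 genes (99.99th percentile), with SLC7A11 (4.55), the glycine transporter gene SLC6A9 (3.17) and SLC1A4 (2.89) highest, but the 13 not in the ATF4 list had one of -0.10 (46.18th percentile). Proteasome subunits had a median of -0.58 over 31 genes (4.11th percentile), with PSMD1 at -1.41.

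Several types of noncoding gene were higher in the FSCN1 siRNA library than random sets of genes matched on mean FPKM. The median log2 ratio was 0.68 over 273 lincRNA genes, 0.31 over 701 antisense genes, 1.16 over 40 sense intronic genes and 0.56 over 116 processed transcripts, each at the 100th percentile of 1000 random sets matched on expression, against -0.10 over 11058 protein-coding genes. Processed pseudogenes went the other way, with a median of -0.25 over 309 genes at the 0th percentile. Antisense and sense intronic genes overlap other genes and strand use is not stated, so their fragments may come from those genes. NEAT1, the scaffold RNA of paraspeckles, read 35 and 567 FPKM, MALAT1 147 and 761 FPKM, and the snoRNA host GAS5 235 and 1270 FPKM, whereas RMRP read 35.6 and 4.46 FPKM. The list of 19 snoRNA host genes had a median of 0.20 at the 97.17th percentile, short of the bound set for it to stand apart. The ratio was also lower at higher expression: of 10 equal groups of genes by mean FPKM, the lowest had a median of 0.42 and the highest -0.40.

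In 8637 genes with mean FPKM of at least 5, each of 15276 7-mers was compared between genes with and without it in the 3' UTR, after regression on UTR length, GC content and mean FPKM. TTATTTA (z 7.16, mean difference 0.14) and TATTTAT (z 6.99, 0.13), the core of AU-rich elements, had the highest scores. The 128 7-mers of A and T alone had a median z of 1.65, which is 0.24 of the TATTTAT score and too near the bound of 0.25 set for it to decide anything about base composition.

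The ATF4 target list had a median log2 ratio of 1.69. Unfolded protein stress in the endoplasmic reticulum could raise the same genes, but it would raise ER chaperones too, and these were at the 0.01st percentile of matched lists. XBP1 (1.49) and ERN1 (1.45) were the 2 members of that list at least 2-fold higher, so a partial response is not excluded. A difference between the cultures other than FSCN1, such as medium or cell density, cannot be told apart from the siRNA with 1 library per group. The hypothesis that lower FSCN1 raises ATF4 targets therefore stays open.

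Off-target silencing may contribute to the lower genes, since an siRNA can act on transcripts that match its seed. The siRNA sequence is not given in the sources used here, so every 7-mer of the FSCN1 transcript was treated as a possible seed match. These 2153 7-mers, 14.1% of all, made up 35 of the 153 7-mers with the lowest scores, where 21.6 were expected, a ratio of 1.62. That lies between the bounds of 1 and 2 set for the test. An siRNA has few seed 7-mers, so a true seed effect need not raise this pooled ratio. The ratio can also reflect other differences in sequence content, so the test cannot decide about off-target silencing. The lowest of all 15276, CTGGCTG, is in FSCN1, and genes with it were lower by a mean difference of only -0.09.

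Of protein-coding genes with at least 1 FPKM in a library, 52 were at 5% or less of control in the FSCN1 siRNA library. The other way round there were 71, so near absence occurred in both directions. These counts do not tell whether the genes of either direction belong together. The tumour suppressor gene CDKN2A (5.34 FPKM), HSD3B1 (5.78), the smooth muscle actin gene ACTG2 (7.06), the cancer-testis antigen genes CTAG2 (3.71) and CTAG1B (3.48), POSTN (0.785) and DCN (0.859) were listed at 0 in the FSCN1 siRNA library, while VIM was lower but present (29.5 and 3.91 FPKM). CTAG2 and CTAG1B were the 2 of 22 cancer-testis genes with mean FPKM of at least 1. CTAG1B has a near-identical copy, so its level is uncertain. Below that mean, most cancer-testis genes with a value above 0 were lower too. Among them were PRAME (0.874 and 0 FPKM), MAGEA3 (0.83 and 0.22 FPKM), MAGEA6 (0.821 and 0.128 FPKM) and MAGEA4 (0.462 and 0 FPKM). MAGEC1 (0 and 0.0477 FPKM) and MAGEC2 (0 and 0.0364 FPKM) were higher, and PAGE1 (0.162 and 0.153 FPKM) hardly differed. All of these are low values that rest on few fragments. Fibroblasts in the control culture could bring POSTN, DCN and COL3A1, and a list of abundant fibroblast transcripts had a median of -0.73 over 10 measured genes (2.09th percentile), 4 at least 2-fold lower and 0 higher, with SPARC at 3.20 and 0.141 FPKM, and BGN (1.13 and 0.0644 FPKM) and THY1 (0.802 and 0.0353 FPKM) were lower below the filter. Against that, COL1A2 and FN1, which fibroblasts make in large amounts, were low, the higher of them at 0.038 times COL3A1 in the control library, and COL1A1 read 7.30 and 6.75 FPKM. The fibroblast list was written after these values were seen and holds COL3A1, SPARC and VIM. Its percentile is therefore not separate support for fibroblasts. With values on both sides, fibroblasts stay open, and cells of another line or other explanations of these genes were not tested.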
